A study of Mus musculus with 8 samples.

How the data were processed

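The samples were 8 libraries of nuclear RNA from NIH3T3 cells, 2 each from untreated cells and from cells under heat shock (44 °C), osmotic stress (200 mM KCl) or oxidative stress (0.2 mM H2O2) for 2 h. Per the labels' protocols, nuclei were enriched by lysis and a sucrose cushion, RNA was treated with DNase, ribosomal RNA was depleted, and strand-specific libraries were made with dUTP and sequenced on an Illumina HiSeq. Per the submitters' processing notes, Bowtie, SAMtools and Cufflinks were used with the mouse genome build mm9. Tool versions, the gene annotation, the strand that was counted and any filter are not given in the sources used here.

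The deposited values are RPKM per gene model per the file headers, made by the authors for each library. They came in 2 tables, for replicates 1 and 2, each with 1 library per group. Both tables list the same 48676 rows, with 44363 distinct names, and 5112 rows share their name with another row. Decimal values and column sums that differ between libraries were checked and do not contradict RPKM. Counts per library are not part of these tables, and no counting intervals were computed. Depth could be estimated only relative to another library, from the RPKM worth of 1 fragment on olfactory receptor rows. That worth was taken as the most frequent value within 1 fixed range of RPKM. An exact 0 can be a failed estimate: 241 values among the tested rows were 0 beside at least 5 RPKM in the other library of the group.

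Each column was assigned to its group and replicate from the table's header, and 0 columns were left unmatched. Values were taken as deposited, 0.5 was added, and log2 was taken. Rows with at least 0.5 RPKM in at least 2 of the 8 libraries were tested, 16056 in all, of which 10299 matched a single protein-coding gene of GENCODE M21 by name. One linear model with the 4 groups was fitted to all 8 libraries in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation and a mean trend (prior degrees of freedom 2.59, residual degrees of freedom 4, median SE of a log2 change 0.21). The 6 comparisons between groups were two-sided, adjusted by Benjamini-Hochberg over the rows tested in each, and called at an adjusted p under 0.05. An exact permutation test of 2 against 2 libraries has a smallest two-sided p of 0.333 and cannot reach 0.05, so the tests rest on the spread shared across genes and groups. In simulated data of the same size, libraries were independent and each gene had 1 spread shared by all groups. There 200 of 16056 rows were changed in each stress: 31.3%, 77.6% and 95.5% of changes by log2 values of 1, 2 and 3 were called for heat shock, 23.9%, 89.6% and 92.4% for osmotic stress and 20.9%, 86.6% and 97% for oxidative stress, with 5 of 141, 5 of 142 and 11 of 147 calls false. The groups of the data did not share 1 spread: the SD of the replicate difference was 0.873 for osmotic stress and 0.525 for heat shock. These shares therefore describe the test under its own assumptions and not its power or error in these data.

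The comparisons, 23 gene lists, rules and alternatives below were fixed before the data were examined, except where said otherwise. Lists were tested against all other rows with limma's camera, with a preset correlation between genes of 0.01, Benjamini-Hochberg over the lists of a comparison, and again with an estimated correlation. The 2 settings differ in more than the correlation. After heat shock the matrix list had an estimated correlation of 0.0039, below the preset one, yet its camera adjusted p went from 0.0014 to 0.24. A call lost in the second setting is therefore, on its own, no evidence of correlation between genes. The matrix list had the lowest estimate, and many lists lay far above the preset value. Estimated correlations were 0.74 for histones, 0.79 for mitosis, 0.73 for DNA replication, 0.72 for NF-kB targets and 0.45 for immediate early genes. For such lists the adjusted p with the preset correlation may be much too small. Within each list, gene p-values were also adjusted over the list alone. The lists cover heat shock chaperones, immediate early genes, NRF2 targets, p53 targets, hyperosmotic response genes, integrated stress response targets, endoplasmic reticulum chaperones, cholesterol synthesis, NF-kB and inflammatory targets, fibroblast matrix, actin and SRF targets, mitosis, DNA replication, histones, ribosomal proteins, nuclear non-coding and snoRNA host genes, splicing, cleavage and termination, mitochondrially encoded genes, hypoxia and glycolysis, circadian output, metallothioneins and zinc export, and markers of other cell types. Btg2, Sesn2, Hspa4l and Slc7a11 are each members of more than 1 list.

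Named rows were the 10 with the largest rise and the 10 with the largest fall for each stress against untreated cells, among those past the threshold, with a mean of at least 1 RPKM over the 8 libraries and the same direction in both tables. For each list they were up to 2 members with the largest rise and up to 2 with the largest fall past the threshold, or else the member with the highest mean. For each pair of stresses they were the 3 rows with the largest difference each way. Since the rule often named short RNAs, pseudogenes and other rows that can share reads, protein-coding genes with large changes were named besides, after their values were seen. Pairs of stresses were compared by the correlation and covariance of log2 changes across rows, against 100 simulations of unchanged groups with the same untreated libraries, and by overlaps of called rows, beside the overlap of independent lists.

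Upstream neighbours were taken from GENCODE M21, whose build differs from that of the tables, by gene name and without coordinates of the tables. A tested row counted as downstream of an expressed gene if its nearest upstream neighbour ended within 10 kb and had a mean of at least 5 RPKM, and 10310 tested rows had a usable neighbour. Neighbours on the opposite strand, whose transcription points away, served as the comparison.

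Alternatives were a filter of 2 RPKM and no filter, pseudocounts of 0.1 and 1, median-of-ratios scaling, columns scaled to a common sum, quantile normalization, no mean trend, the replicate number as a block, only the 2 groups compared, other neighbour limits, and leaving out each library. After the data were seen, 2 were added: doubtful zeros set to missing, and protein-coding rows only. In osmotic stress replicate 1 a single row, AC113316.1, held 1025000 of 1943000 RPKM, so scaling to a common sum lowers every other row there. Since all comparisons share 1 estimate of the spread, that scaling can also end calls that do not involve osmotic stress. Tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Reads were not analysed here, so reads past gene ends were not measured directly.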

Results

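Nuclear RNA of NIH3T3 cells, a line of mouse embryonic fibroblasts, was sequenced in untreated cells and after 2 h of heat shock at 44 °C, osmotic stress with 200 mM KCl or oxidative stress with 0.2 mM H2O2. Each of the 4 groups had 2 libraries, and each of the 2 deposited tables held 1 library per group. The tables gave RPKM, read counts scaled to gene length and mapped reads, for 48676 gene models, of which 16056 reached 0.5 RPKM in at least 2 libraries and were tested. Across these rows, the log2 values of the 2 libraries of a group correlated with r = 0.966 for untreated cells, 0.969 for heat shock, 0.926 for osmotic stress and 0.956 for oxidative stress (genes are not independent replicates). The RPKM values of a library summed to between 503400 and 771700, apart from osmotic stress replicate 1 with 1943000. In that library 1 row, AC113316.1, held 1025000 RPKM, and the abundant nuclear RNA Malat1 was listed at 0 against 1840 to 2330 RPKM in the other libraries. On olfactory receptor rows, the most frequent value within a fixed range was taken as 1 fragment. It was 0.0147 to 0.0152 RPKM in the libraries of replicate 1 and 0.0189 to 0.0207 RPKM in those of replicate 2. By this value the depth of each stress library was 0.971 to 1.06 times that of the untreated library of its table. In a much deeper library several fragments could give a value in the same range, so a large difference in depth is not excluded. The labels do not say whether the libraries came from separate cultures, so p-values measure the spread between these samples, which may be technical.

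The series title names transcription that reads through gene ends under stress, and the first comparison was of heat-shocked with untreated cells. Among the genes that rose were 17 of the 24 chaperone genes of a fixed list. Hspa1a and Hspa1b, which encode the inducible HSP70 chaperone, were at 268 ± 21.5 and 496 ± 55.6 RPKM after heat shock against 2.12 ± 0.279 and 6.13 ± 0.396 RPKM in untreated cells (mean ± SD, n = 2 libraries per group). On the log2(RPKM + 0.5) scale, which understates the change of low genes, they were higher by 6.68 (SE 0.19) and 6.22 (SE 0.17), both with limma adjusted p = 3.3e-05. The 2 genes are near-identical copies, so their separate values are uncertain. The HSP110 gene Hsph1 rose from 24.4 ± 4.79 to 560 ± 36.3 RPKM, and the HSP40 genes Dnajb1 and Dnaja1 rose from 23.8 ± 6.98 to 535 ± 53.7 and from 16.6 ± 2.72 to 321 ± 5.53 RPKM.

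Of the 24 chaperone genes of the fixed list, 17 rose, 0 fell and 7 did not pass the test, with a median log2 change of 1.78. Adjusted over the list alone, 19 rose. Besides those named, Hsp90aa1, Hspa8, Hspe1, Hspb8, Cryab, Bag3, Chordc1 and others passed. The camera test of the list against all other genes gave adjusted p = 5.1e-23 with a preset correlation, and adjusted p = 0.15 with an estimated correlation. Outside the list, Phlda1 rose by a log2 change of 4.74 (SE 0.29, limma adjusted p = 0.00076) and Tmem44 by 4.17 (SE 0.3, limma adjusted p = 0.0016). The small heat shock protein gene Hspb1 was listed at 0 in both untreated libraries and at 12.5 and 6.75 RPKM after heat shock. Ccdc107 was listed at 15.9 and 14.1 RPKM after heat shock and at 0 in every other library. The RNase MRP rows given below show the same pattern, so a failed estimate is possible for Ccdc107 too. The calls of Hspa1a, Hspa1b, Hsph1, Dnajb1, Dnaja1, Phlda1 and Tmem44 held in all 8 fits that left out 1 library.

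Among 22 immediate early genes, which respond first to many stimuli, Klf6, Dusp1 and Jun rose, Ier3 fell and 18 did not pass. Adjusted over the list alone, 6 rose and 1 fell (median log2 change 0.35, camera adjusted p = 4e-04, or adjusted p = 0.8 with an estimated correlation). Dusp1, a phosphatase of stress kinases, went from 2.85 ± 0.0203 to 32.8 ± 2.6 RPKM, and Jun from 11 ± 2.35 to 90.3 ± 0.922 RPKM. Without heat shock replicate 1, the limma adjusted p of Jun was 0.059. Of 25 integrated stress response genes, Ppp1r15a, Ddit4 and Cebpb rose and the amino acid transporter gene Slc3a2 fell (3 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.99). Ppp1r15a, which encodes the stress-induced subunit of an eIF2α phosphatase, rose by 2.57 on the log2 scale (SE 0.22, limma adjusted p = 0.0044), and its adjusted p was 0.053 without untreated replicate 1.

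Single histone, ribosomal protein and matrix genes fell after heat shock. Of 56 replication-dependent histone genes, 23 fell and 0 rose (38 fell adjusted over the list alone). Their median log2 change was -1.28, with camera adjusted p = 5.1e-13, or adjusted p = 0.8 with an estimated correlation. Histone H1 genes Hist1h1b and Hist1h1d went from 475 ± 19.8 to 109 ± 19 and from 468 ± 101 to 120 ± 31.5 RPKM. Histone copies can share reads, so single histone genes are uncertain. Of 74 cytosolic ribosomal protein genes, 15 fell and 0 rose (43 and 1 adjusted over the list alone, median -0.62, camera adjusted p = 6.2e-14, or adjusted p = 0.48 with an estimated correlation). Rpl26 fell by 1.68 (SE 0.26) and Rps2 by 1.44 (SE 0.17) on the log2 scale. Of 20 extracellular matrix genes, Fn1, Sparc and Bgn fell (4 adjusted over the list alone, median -0.61, camera adjusted p = 0.0014, or adjusted p = 0.24 with an estimated correlation). The fibronectin gene Fn1 went from 341 ± 91 to 110 ± 24 RPKM. Of 12 nuclear non-coding and snoRNA host genes, Mir17hg, Snhg8, Snhg3 and Snhg5 fell (6 adjusted over the list alone, median -0.57, camera adjusted p = 0.0011, or adjusted p = 0.48 with an estimated correlation). Mir17hg, the host of the miR-17 cluster, went from 4.47 ± 0.191 to 0.337 ± 0.0464 RPKM and kept its call in all 8 fits that left out 1 library. The medians of these 4 lists stayed below 0 under each scaling tried.

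For endoplasmic reticulum chaperones and cholesterol synthesis, the sign of the median log2 change depended on the scaling of the libraries. Scaling columns to a common sum moves the rows of a library together, while camera tests a list relative to the other rows. Of 18 endoplasmic reticulum chaperone genes, Calr, Pdia6 and Hyou1 fell (8 adjusted over the list alone), and Calr went from 671 ± 5.22 to 260 ± 16.1 RPKM. The list's median was -0.43 (camera adjusted p = 0.00035, or adjusted p = 0.8 with an estimated correlation) and 0.03 with columns scaled to a common sum. Of 21 cholesterol synthesis genes, Dhcr7, Mvd and Nsdhl fell (5 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 0.0096, or adjusted p = 0.81 with an estimated correlation) and of 0.06 with that scaling. Without heat shock replicate 1 the cholesterol list had camera adjusted p = 0.073. None of the 11 mitochondrially encoded genes passed, by either adjustment, and all 11 lay below 0 (median -0.76, camera adjusted p = 0.024, or adjusted p = 0.8 with an estimated correlation). That list's adjusted p was 0.11 without untreated replicate 1 and 0.14 without heat shock replicate 1. The calls of Calr, Fn1, Rps2, Rpl26 and Hist1h1b ended with columns scaled to a common sum, where limma adjusted p was 0.74, 0.54, 0.62, 0.47 and 0.19. So did those of Pdia6, Nsdhl, Dhcr7, Bgn, Hist1h1d, Ier3 and Slc3a2 (0.81, 0.75, 0.82, 0.54, 0.28, 0.72 and 0.86), and with quantile normalization those of Calr, Pdia6 and Ier3 (0.25, 0.21 and 0.058). Calr, Fn1, Rps2, Rpl26 and Hist1h1b kept their calls with median-of-ratios scaling (limma adjusted p = 0.024, 0.028, 0.012, 0.028 and 0.0057). With the common sum their log2 changes were -0.89, -1.14, -0.98, -1.23 and -1.65. That scaling lowers osmotic stress replicate 1, whose sum 1 row dominates, and can widen the spread shared by all comparisons. In the 8 fits that left out 1 library, Hist1h1b lost its call only without untreated replicate 1 (adjusted p = 0.062). Calr, Rps2, Rpl26, Hist1h1d and Snhg8 lost theirs without any 1 of the untreated or heat shock libraries, and Fn1 also without either oxidative stress library.

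Besides the integrated stress response list, 13 lists were not called after heat shock. Of 21 p53 targets, Ccng1 rose (camera adjusted p = 0.24), and of 19 NRF2 targets, which answer oxidants, G6pdx fell (adjusted p = 0.91). Of 9 hyperosmotic response genes, the taurine transporter gene Slc6a6 fell (adjusted p = 0.99). Vcl fell among 15 actin and SRF target genes (adjusted p = 0.34), and Tra2b rose and Srsf5 fell among 19 splicing genes (adjusted p = 0.48). Cpsf3, Ints4 and Ints12 fell among 35 cleavage, polyadenylation and termination factors (adjusted p = 0.99), and P4ha1, Hk2 and Pgk1 fell among 14 hypoxia and glycolysis genes (adjusted p = 0.24). Des and Cd68 fell among 11 markers of other cell types (adjusted p = 0.24). Adjusted over the list alone, these lists gave 1 and 0 genes that rose and fell for p53, 1 and 3 for NRF2, 0 and 1 for hyperosmotic, 0 and 3 for actin, 1 and 1 for splicing, 0 and 5 for termination, 1 and 5 for hypoxia and 0 and 3 for other cell types. No gene passed among 16 NF-kB targets (adjusted p = 0.82), 16 mitosis genes (adjusted p = 0.99), 16 DNA replication genes (adjusted p = 0.24), 10 circadian genes (adjusted p = 0.82) and 3 metallothionein and zinc export genes (adjusted p = 0.34). Over the list alone 1 metallothionein or zinc export gene rose and 0 genes of the other 4 lists passed. Medians of the NRF2, NF-kB, termination and circadian lists lay near 0 (0.10, 0.01, -0.01 and -0.07), with means of -0.11, -0.06, -0.09 and 0.01 and camera direction up in each. Camera adjusted p was 0.011 for hypoxia without heat shock replicate 2, 0.04 for actin without untreated replicate 2 and 0.033 for metallothioneins and zinc export without untreated replicate 1. With columns scaled to a common sum, the calls of Ccng1, G6pdx, Slc6a6, Vcl, Tra2b and Srsf5 ended (limma adjusted p = 0.22, 0.81, 0.8, 0.67, 0.18 and 0.84), as did those of Cpsf3, Ints12, P4ha1, Hk2, Des and Cd68 (0.8, 0.79, 0.89, 0.68, 0.91 and 0.69). With quantile normalization those of G6pdx, Slc6a6, P4ha1 and Des ended (0.051, 0.052, 0.067 and 0.051). With the common sum the rises of Ccng1 and Tra2b were larger than as deposited, at 1.52 and 1.53 against 1.04 and 1.05. The falls of the other named genes were smaller, from -0.33 for Des to -0.90 for Vcl and Hk2.

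In all, limma called 1063 rows between heat shock and untreated cells, 408 higher and 655 lower, and 263 and 319 of them by at least 2-fold. The split of higher and lower calls was 794 and 635 with median-of-ratios scaling, 304 and 60 with columns scaled to a common sum and 708 and 565 with quantile normalization. The count fell to 73 without untreated replicate 1, 142 without untreated replicate 2, 81 and 117 without heat shock replicates 1 and 2, and 494 and 492 without oxidative stress replicates 1 and 2, and 50 of the 1063 calls held in all 8 such fits. Among short RNAs, which can share reads and whose zeros can be failed estimates, a row of the RNA component of RNase MRP was listed at 0 in both untreated libraries and at 80000 and 52700 RPKM after heat shock. The row Rmrp, for the same RNA, was listed at 0 and then at 865 and 1160 RPKM. Rows named SNORD58, SNORD60, Snord110 and Mirlet7f-1 were listed at 0 in both heat shock libraries and at 226 and 937, 388 and 339, 265 and 122, and 48.9 and 38.3 RPKM in untreated ones. A vault RNA row went from 31.5 and 52.6 RPKM to under 0.001 RPKM in both heat shock libraries. The pseudogene rows Gm12455 and Gm12851 and the rows AK217986, C920011F04Rik and mKIAA0676, which may hold reads of related genes, rose by log2 changes of 6.58, 5.69, 6.37, 6.19 and 5.20, and AK019262, 2210403K04Rik and mKIAA1839 fell by 3.35, 3.10 and 2.68.

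**Figure D1:**
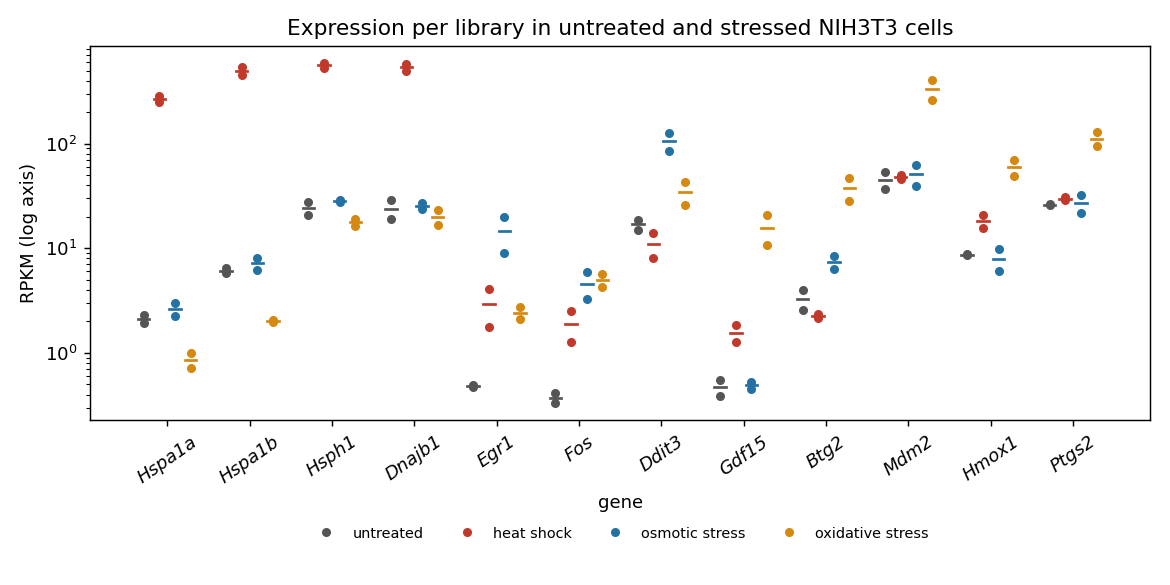
RPKM on a log axis of 12 genes in the 4 groups, with 1 point per library and a bar at the mean of each group. Hspa1a, Hspa1b, Hsph1 and Dnajb1 sit highest in the 2 heat shock libraries, Egr1 and Ddit3 in the 2 osmotic stress libraries, and Gdf15, Btg2, Mdm2, Hmox1 and Ptgs2 in the 2 oxidative stress libraries.

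Osmotic stress was next compared with untreated cells. The transcription factor genes Egr1, Fos, Jund and Ddit3 were among those that rose. Egr1, a zinc finger factor, went from 0.481 ± 0.00986 to 14.5 ± 7.67 RPKM (mean ± SD, n = 2 libraries per group), a log2 change of 3.83 (SE 0.44, limma adjusted p = 0.027). Fos went from 0.37 ± 0.056 to 4.61 ± 1.93 RPKM and Jund, another AP-1 gene, from 41 ± 8.52 to 122 ± 16.3 RPKM. Ddit3, the stress factor CHOP, went from 17 ± 2.61 to 106 ± 28.5 RPKM (log2 change 2.59, SE 0.36, limma adjusted p = 0.043). Egr1, Fos and Ddit3 stood higher in osmotic stress replicate 1, the library with Malat1 listed at 0, than in replicate 2. The values were 19.9 and 9.06, 5.97 and 3.24, and 126 and 86 RPKM, all above both untreated libraries. The log2 change of Egr1 was 4.38 without osmotic stress replicate 2 and 3.28 without replicate 1. Hexim1, an inhibitor of the elongation factor P-TEFb, went from 13.7 ± 1.53 to 61.1 ± 26.2 RPKM, and the phosphate transporter gene Slc20a1 from 21.1 ± 0.63 to 74.9 ± 14.3 RPKM.

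Also higher were Vmac, Caprin2 and Cdkn2aip, by log2 changes of 2.74 (SE 0.25), 2.56 (SE 0.22) and 1.75 (SE 0.15), and Hnrnpd by 1.42 (SE 0.2). The focal adhesion gene Vcl went from 93.2 ± 8.41 to 34.3 ± 2.57 RPKM, Srsf5 from 75.7 ± 5.47 to 32.3 ± 1 RPKM, Iqgap1 from 161 ± 27.2 to 66.2 ± 2.85 RPKM and Ppp1r10 from 47.2 ± 5.51 to 20.9 ± 0.361 RPKM. Egr1 and Fos kept their calls with columns scaled to a common sum (limma adjusted p = 9.6e-05 and 0.032), as did Vmac (0.03), while those of Ddit3, Hexim1, Slc20a1, Jund and Vcl ended there (0.088, 0.33, 0.62, 0.78 and 0.051). The calls of Caprin2, Cdkn2aip, Hnrnpd, Srsf5, Iqgap1 and Ppp1r10 also ended with that scaling (0.056, 0.64, 0.84, 0.11, 0.11 and 0.12). The falls of Vcl, Srsf5, Iqgap1 and Ppp1r10 were larger with it, at -2.09, -1.87, -1.93 and -1.81 against -1.43, -1.21, -1.26 and -1.15 as deposited. The rises were smaller, at 1.93 for Ddit3, 1.40 for Hexim1, 1.13 for Slc20a1, 0.91 for Jund, 1.99 for Caprin2, 1.11 for Cdkn2aip and 0.76 for Hnrnpd. Hnrnpd lost its call with median-of-ratios scaling too (0.052), and Hnrnpd, Fos and Iqgap1 with quantile normalization (0.063, 0.051 and 0.051). Egr1, Fos, Ddit3, Hexim1, Slc20a1, Jund, Vcl and Srsf5 each passed in 1 of the 8 fits that left out 1 library and Vmac in 2, with Egr1 at log2 changes of 3.28 to 4.38 and adjusted p up to 0.18.

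All 22 immediate early genes lay above 0 under osmotic stress, 2 of them past the threshold (9 rose and 0 fell adjusted over the list alone, median 0.59, camera adjusted p = 0.00052, or adjusted p = 0.9 with an estimated correlation). The median of all tested rows was 0.18 as deposited, 0.00 with median-of-ratios scaling, -0.37 with columns scaled to a common sum and 0.02 with quantile normalization, and camera tests each list relative to the other rows. On that relative scale, 5 further lists were lower. Of 20 matrix genes 0 passed, also over the list alone, and 18 lay below 0 (median -0.37, camera adjusted p = 0.00044, or adjusted p = 0.25 with an estimated correlation). Cholesterol synthesis (21 genes, median -0.15, camera adjusted p = 0.01) and endoplasmic reticulum chaperones (18 genes, median -0.06, adjusted p = 0.013) also had 0 genes past the threshold, by either adjustment. Mitochondrially encoded genes had 0 of 11 (1 rose and 1 fell adjusted over the list alone, median -0.27, adjusted p = 0.013). Of the 12 nuclear non-coding and snoRNA host genes, Mir17hg fell from 4.47 ± 0.191 to 0.69 ± 0.009 RPKM (2 rose and 2 fell adjusted over the list alone, median -0.14, mean -0.59, adjusted p = 0.024). This call and mean rest on Malat1, listed at 0 in osmotic stress replicate 1 and at 2040 RPKM in replicate 2: with doubtful zeros missing the mean was -0.09, the median -0.07 and the adjusted p 0.058. With an estimated correlation, these 4 lists had adjusted p = 0.9 each. Without osmotic stress replicate 1, camera adjusted p was 0.17 for cholesterol synthesis and 0.25 for endoplasmic reticulum chaperones. It was 0.25 for the latter and 0.053 for the non-coding and host genes without untreated replicate 2, and 0.07 for mitochondrially encoded genes without untreated replicate 1.

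The genes known to serve the response to hypertonic medium did not pass. Of 9 hyperosmotic response genes, which hold transporters and enzymes of compatible solutes, 0 passed by either adjustment (median 0.10, camera adjusted p = 0.36), and the water channel gene Aqp1 was at 96.3 ± 0.128 RPKM against 116 ± 25.7 RPKM. Of 24 chaperone genes 0 passed by either adjustment (median 0.22, adjusted p = 0.6), with Hsp90ab1 at a log2 change of -0.24. Ddit3 was the only one of 25 integrated stress response genes to pass over all genes (7 rose and 0 fell adjusted over the list alone, adjusted p = 0.36). Of 19 NRF2 targets 0 passed (5 rose and 0 fell adjusted over the list alone, adjusted p = 0.55). Vcl fell among actin genes (1 over the list alone, adjusted p = 0.28) and Srsf5 among splicing genes (1 over the list alone, adjusted p = 0.067). For hypoxia genes 0 passed (2 fell adjusted over the list alone, adjusted p = 0.073) and for circadian genes 0 passed (1 rose adjusted over the list alone, adjusted p = 0.8). No gene passed by either adjustment among p53 targets (adjusted p = 0.27), NF-kB targets (0.74), mitosis genes (0.36), DNA replication genes (0.23), histones (0.57), ribosomal proteins (0.27), termination factors (0.36), metallothionein and zinc export genes (0.7) and markers of other cell types (0.8). The median was above 0 and the camera direction down for the hyperosmotic, actin, mitosis, replication, ribosomal protein, termination, metallothionein and other cell type lists, and the replication mean was -0.02. Without osmotic stress replicate 1, camera adjusted p was 0.00025 for mitosis (median -0.27), 0.00095 for replication (-0.20), 0.00025 for splicing (-0.30), 0.011 for actin (-0.27) and 0.024 for integrated stress response genes (0.20). Without osmotic stress replicate 2 it was 0.0025 for histones (median 0.56), 0.0061 for ribosomal proteins (0.03) and 0.0085 for hypoxia genes (-0.26). It was 0.045 for splicing and 0.031 for hypoxia without untreated replicate 1, and 0.019 for actin and 0.02 for replication without untreated replicate 2. The medians of 15 of the 23 lists changed sign under another scaling.

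Limma called 111 rows between osmotic stress and untreated cells, 69 higher and 42 lower, and 3545 rows had an unadjusted p under 0.05. The split was 51 and 90 with median-of-ratios scaling, 66 and 78 with columns scaled to a common sum and 57 and 81 with quantile normalization. The count was 22 without osmotic stress replicate 1 and 777 without osmotic stress replicate 2, 9 and 8 without untreated replicates 1 and 2, 10 without either heat shock library and 21 without either oxidative stress library, and 4 of the 111 calls held in all 8 fits. Among short and repeated RNAs, given as uncertain, the mitochondrial tRNA row mt-Tc was listed at 0 in both osmotic stress libraries and at 315 and 434 RPKM in untreated ones. Rows named SNORD58, Snord110 and SNORD70 were also listed at 0 in both osmotic stress libraries, the last against 16.9 and 47.5 RPKM. Of 940 rows named U6, U6#148 was listed at 0 in untreated cells and at 146 and 23 RPKM under osmotic stress, U6#775 went from 7.08 and 7.33 to 120 and 52.7 RPKM, and U6#238 and U6#323 were listed at 0 under osmotic stress and at 11.8 and 8.31 and at 7.08 and 7.33 RPKM in untreated cells. The pseudogene rows Gm12306 and Gm11631 were listed at 0 in untreated cells and at 44.9 and 23.2 and at 9.97 and 3.08 RPKM under osmotic stress. Rows Gm14162, 4933433C11Rik, Snhg20 and AK006031 rose by log2 changes of 4.24, 3.36, 3.14 and 3.08, and LOC100302567, AK141672, D4Wsu53e and Gm6635 fell by 4.05, 3.96, 2.22 and 2.21.

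Oxidative stress was then compared with untreated cells, and genes of the p53 response rose. Gdf15, which encodes a secreted stress factor, went from 0.471 ± 0.113 to 15.6 ± 6.96 RPKM (mean ± SD, n = 2 libraries per group), a log2 change of 3.99 (SE 0.32, limma adjusted p = 0.011). Mdm2, the ubiquitin ligase of p53, went from 45.2 ± 11.8 to 335 ± 103 RPKM, the antiproliferative gene Btg2 from 3.27 ± 1.01 to 37.4 ± 13.1 RPKM and Trp53inp1 from 4.63 ± 0.35 to 32.9 ± 5.72 RPKM. Of 21 p53 targets, 10 rose, 0 fell and 11 did not pass, with a median log2 change of 1.33. The other members that rose were the death receptor gene Fas, Bbc3, Sesn2, Polk, Plk3 and Eda2r. Fas stood at 20.2 and 7.35 RPKM in oxidative stress replicates 1 and 2. With 1 library left out, its log2 change ranged from 1.92 to 3.32 and that of Sesn2 from 1.50 to 2.15. Adjusted over the list alone, 16 rose, and camera gave adjusted p = 5e-14, or adjusted p = 0.38 with an estimated correlation.

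Single immediate early, inflammatory and integrated stress response genes also rose. Of 22 immediate early genes, Btg2, Fos, Dusp1 and Jun rose (14 rose and 0 fell adjusted over the list alone, median 1.06, camera adjusted p = 3.7e-13, or adjusted p = 0.38 with an estimated correlation). Fos went from 0.37 ± 0.056 to 4.95 ± 0.938 RPKM, and its log2 change ranged from 2.46 to 2.81 with 1 library left out. Of 16 NF-kB and inflammatory targets, Ptgs2, the inducible cyclooxygenase, rose from 26 ± 0.406 to 112 ± 24 RPKM (3 rose and 0 fell adjusted over the list alone, median 0.94, camera adjusted p = 5.3e-05, or adjusted p = 0.56 with an estimated correlation). Several members stood higher in oxidative stress replicate 1 than in replicate 2, with Tnfaip3 at 53.2 and 4.09, Nfkbia at 107 and 28.6 and Cxcl1 at 79.2 and 19.6 RPKM. The list's median was 0.39 without replicate 1 (adjusted p = 0.011) and 1.54 without replicate 2 (adjusted p = 1.9e-10) of oxidative stress. Of 25 integrated stress response genes, Sesn2, Cebpg and Ppp1r15a rose (8 and 0 adjusted over the list alone, median 0.17, camera adjusted p = 1.2e-05, or adjusted p = 0.38 with an estimated correlation). The growth factor gene Ereg rose by a log2 change of 2.73 (SE 0.16, limma adjusted p = 0.0029) and was past the threshold in all 8 fits that left out 1 library, with adjusted p up to 0.042. Gdf15 passed in 6 of them, Trp53inp1 in 5, and Btg2, Mdm2, Hmox1 and Ptgs2 in 3 each.

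The lists of genes that answer oxidants and metals were called in camera, with 1 gene past the threshold between them. Of 19 NRF2 targets, Hmox1, the heme oxygenase gene, rose from 8.66 ± 0.0933 to 59.5 ± 14.8 RPKM and 18 did not pass (2 rose and 0 fell adjusted over the list alone). The list's median was 0.11 and its mean 0.47, with camera adjusted p = 0.0017, or adjusted p = 0.38 with an estimated correlation and adjusted p = 0.054 without untreated replicate 2. Of 3 metallothionein and zinc export genes 0 passed over all genes (3 rose adjusted over the list alone, median 1.27, camera adjusted p = 0.0017, or adjusted p = 0.38 with an estimated correlation), and Mt1 was at 168 ± 19 against 93.4 ± 33.5 RPKM. Of 11 markers of other cell types, Cdh1, the epithelial cadherin, rose from 0.0235 ± 4.99e-05 to 0.835 ± 0.244 RPKM (4 rose and 0 fell adjusted over the list alone, median 0.16, camera adjusted p = 0.004, or adjusted p = 0.38 with an estimated correlation). These 11 of 39 markers passed the filter on low values. Cdh1, Pecam1 and Tubb3 reached 0.5 RPKM only in the 2 oxidative stress libraries, so the filter admitted them through their rise, which favours a rise of this list. Vegfa rose by 1.17 (SE 0.17, limma adjusted p = 0.036) among 14 hypoxia genes, and passed in 0 of the 8 fits that left out 1 library. Its call ended with columns scaled to a common sum (limma adjusted p = 0.4) and with quantile normalization (0.06), although its log2 changes there were 1.37 and 1.26. The call of Cdh1 ended with quantile normalization (0.078) and held in 1 of the 8 fits. The hypoxia list was not called (2 rose and 1 fell adjusted over the list alone, median -0.15, mean 0.06, camera adjusted p = 0.82).

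The histone, mitosis and DNA replication lists had camera direction down under oxidative stress. Of 56 histone genes 0 passed over all genes (1 rose and 25 fell adjusted over the list alone), and 54 lay below 0 (median -0.87, camera adjusted p = 1.2e-13, or adjusted p = 0.53 with an estimated correlation). Of 2 rows of the histone gene Hist2h2aa1, the one not counted in the list went from 69.1 ± 8.02 to 27.4 ± 0.369 RPKM. For 16 mitosis genes (0 passed by either adjustment, 15 below 0, median -0.68) camera gave adjusted p = 0.0065, or adjusted p = 0.75 with an estimated correlation. For 16 DNA replication genes (0 passed, 1 fell adjusted over the list alone, all 16 below 0, median -0.44) it gave adjusted p = 0.0029, or adjusted p = 0.74 with an estimated correlation. All 21 cholesterol synthesis genes lay below 0, and 1 row of Hmgcs1 fell by 0.96 on the log2 scale (3 fell adjusted over the list alone, median -0.48, camera adjusted p = 3e-06, or adjusted p = 0.43 with an estimated correlation). The call of that Hmgcs1 row ended with columns scaled to a common sum (limma adjusted p = 1) and with quantile normalization (0.075), and held in 0 of the 8 fits that left out 1 library. That of the Hist2h2aa1 row ended with the first of these scalings (0.65). The log2 changes with that scaling were -1.12 for the Hist2h2aa1 row and -0.77 for the Hmgcs1 row. Actin and SRF targets (15 genes, median -0.41, 1 fell adjusted over the list alone, camera adjusted p = 0.03) and cleavage, polyadenylation and termination factors (35 genes, median -0.21, 1 fell adjusted over the list alone, camera adjusted p = 0.044) had 0 genes past the threshold over all genes, and adjusted p = 0.75 each with an estimated correlation. Without untreated replicate 1, camera adjusted p was 0.15 for mitosis, 0.39 for actin and 0.1 for termination factors. Without oxidative stress replicate 2 it was 0.15 for mitosis, 0.1 for DNA replication and 0.19 for actin, and for termination factors it was 0.22 without oxidative stress replicate 1 and 0.052 without either osmotic stress library. None of the medians of the 13 called lists changed sign under another scaling.

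The remaining lists were not called. Among 24 chaperones Hspa1b fell from 6.13 ± 0.396 to 2.03 ± 0.0665 RPKM (3 fell adjusted over the list alone, median -0.26, camera adjusted p = 0.087), with the same doubt about its near-identical copy. Snhg5 fell among nuclear non-coding and snoRNA host genes (1 over the list alone, adjusted p = 0.66). Hyperosmotic response genes had 0 past the threshold over all genes and 1 that rose over the list alone (adjusted p = 0.95). Matrix genes (adjusted p = 0.055), endoplasmic reticulum chaperones (0.95), ribosomal proteins (0.6), splicing genes (0.66), mitochondrially encoded genes (0.1) and circadian genes (0.6) had 0 by either adjustment. Adjusted p was 0.046 for matrix genes and 0.021 for mitochondrially encoded genes without either heat shock library, 0.037 for the latter without untreated replicate 1, and 0.021 for ribosomal proteins without oxidative stress replicate 2. The camera direction was up against a negative or zero median for the hyperosmotic (-0.06), ribosomal protein (0.00), splicing (-0.03) and hypoxia lists. Among single genes Gas1 fell by 1.65 (SE 0.27, limma adjusted p = 0.047), Hyls1 by 1.55, Pwwp2b by 1.29 and the spliceosome core gene Prpf8 by 1.16. Hspa1b passed in 2 of the 8 fits that left out 1 library, Gas1 and Prpf8 in 1 each, and Hyls1, Pwwp2b and Snhg5 in 0. With columns scaled to a common sum, the calls of Gas1, Hyls1, Pwwp2b, Prpf8, Hspa1b and Snhg5 ended (limma adjusted p = 0.29, 0.28, 0.61, 0.95, 0.5 and 1). With quantile normalization those of Gas1, Prpf8 and Snhg5 ended (0.059, 0.061 and 0.058). With the common sum the log2 changes of Gas1, Hyls1, Pwwp2b, Prpf8, Hspa1b and Snhg5 were -1.49, -1.43, -1.16, -0.97, -1.27 and -0.71, somewhat smaller than as deposited.

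Limma called 238 rows between oxidative stress and untreated cells, 207 higher and 31 lower, and 2869 rows had an unadjusted p under 0.05. The split was 469 and 45 with median-of-ratios scaling, 257 and 25 with columns scaled to a common sum and 153 and 27 with quantile normalization. The count was 15 without oxidative stress replicate 1, 11 and 13 without untreated replicates 1 and 2, 14 without either heat shock library and 78 and 79 without osmotic stress replicates 1 and 2, and 7 of the 238 calls held in all 8 fits. It was 33 when rows needed 2 RPKM in at least 2 libraries. Rows given as uncertain included SNORD63 and Scarna9, listed at 0 in both untreated libraries and at 113 and 106 and at 55.7 and 52 RPKM under oxidative stress. The snoRNA rows SNORA72#2, SNORA32#2 and Snord14d, at or near 0 in untreated cells, stood at 43.6 and 7.01, 16.4 and 14.9, and 23.5 and 6.17 RPKM, and AL929371.2 and a U6 row, listed at 0 there, at 3.77 and 7.89 and at 7.91 and 2.72 RPKM. Row 1810011O10Rik rose by a log2 change of 3.22. C430049B03Rik and AK079263 fell by 1.71 and 1.41, calls that ended with columns scaled to a common sum (limma adjusted p = 0.21 and 0.2), at log2 changes of -1.58 and -1.43. The rows mt-Tc, Snord110 and U6#238 were listed at 0 in both oxidative stress libraries, as under osmotic stress.

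**Figure D2:**
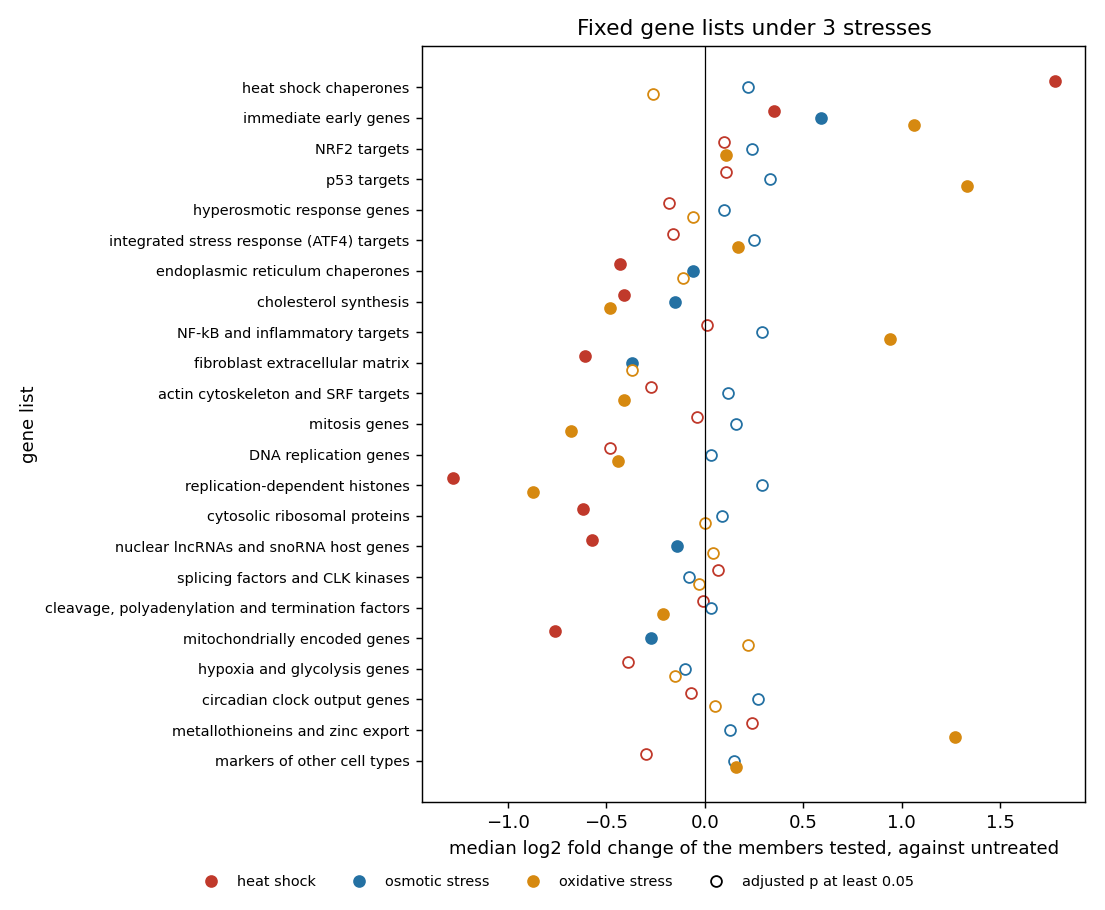
Median log2 fold change against untreated cells of the members tested of each of 23 fixed gene lists, with 1 point per stress, filled where camera adjusted p was under 0.05 with the preset correlation. With an estimated correlation none was, and the lowest adjusted p was 0.15. Chaperones reached 1.78 after heat shock and p53 targets 1.33 under oxidative stress, while histones lay at -1.28 and -0.87 there; under another scaling 9, 15 and 5 of the 23 medians change sign for heat shock, osmotic and oxidative stress, among called lists those of endoplasmic reticulum chaperones and cholesterol synthesis after heat shock.

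The 3 responses were then set beside each other. Primpol, a primase-polymerase gene, and AK050795 were called higher under all 3 stresses, by log2 changes for Primpol of 1.52, 1.42 and 1.35 for heat shock, osmotic and oxidative stress. Spna2, which encodes a spectrin chain, was called lower under all 3, by -0.98, -0.92 and -0.96, together with the short RNA rows U6#238, Snord110 and Mir210. The 3 comparisons use the same 2 untreated libraries, so a deviating untreated value alone would give like changes in each. These calls are therefore not 3 independent results. Jund and Zfp36l1 were among 17 rows higher under both heat shock and osmotic stress, and Vcl, Srsf5, Iqgap1 and Mir17hg among 24 lower under both, against 1.75 and 1.71 for independent lists of those sizes, which leaves out that the comparisons share their untreated libraries. Heat shock and oxidative stress shared 18 higher rows, with Jun, Dusp1 and Ppp1r15a, and 13 lower rows, with Prpf8 and Snhg5, against 5.26 and 1.26. Osmotic and oxidative stress shared 7 higher rows, with Fos and Rhob, and 5 lower rows, against 0.89 and 0.0811. Unchanged groups simulated against the same untreated libraries shared 0.03 higher and 0.02 lower rows on average, a value near 0 because such groups give almost no calls. That value leaves out the effects and the other the shared libraries, so part of each excess may come from the shared libraries.

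Across the 16056 rows (genes are not independent replicates), log2 changes of heat shock and osmotic stress correlated with r = 0.442, those of heat shock and oxidative stress with 0.286 and those of osmotic and oxidative stress with 0.21. Since all use the same untreated libraries, unchanged groups gave r = 0.499 in 100 simulations. That value follows from the shared libraries alone, and changes in 1 stress only lower r. An r below it therefore does not show that responses are less alike than in unchanged groups. The covariances were 0.209, 0.114 and 0.0768 against 0.0754 in simulations, a difference of 0.133, 0.0389 and 0.00138. The simulations gave each gene 1 spread in all groups, which the data did not share, so a difference as small as 0.00138 shows no shared response. Between tables, which share no library, the covariance was 0.102 and 0.171 for heat shock and osmotic stress, 0.0362 and 0.0399 for heat shock and oxidative stress, and 0.0172 and -0.0236 for osmotic and oxidative stress. The correlation of osmotic and oxidative stress was 0.341 without untreated replicate 1 and 0.363 without untreated replicate 2, where unchanged groups gave 0.667 each, and the covariance differed from the simulated one by -0.00299 and 0.0149.

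The stresses were also tested against each other. Hspa1a stood at 268 ± 21.5 RPKM after heat shock against 2.61 ± 0.539 RPKM under osmotic stress (mean ± SD, n = 2 libraries per group), a log2 difference of 6.44 (SE 0.19, limma adjusted p = 3.5e-05), and Phlda1 and Dnajb1 differed by 4.60 and 4.37. Vmac was lower after heat shock than under osmotic stress, by -2.98 (SE 0.25, limma adjusted p = 0.004), as were Nabp1 and Kat6a, by -2.85 and -3.29, both past the threshold in 3 of the 8 fits that left out 1 library. Kat6a stood at 0.00942 ± 0.00668 RPKM after heat shock and at 4.95 ± 3.17 RPKM under osmotic stress, so a failed estimate is possible for it. 9430037G07Rik was lower after heat shock and higher under osmotic stress, each past the threshold. Limma called 1316 rows, 286 higher and 1030 lower after heat shock, where the median of all rows was -0.26. The split was 364 and 196 with median-of-ratios scaling, 479 and 67 with columns scaled to a common sum and 339 and 208 with quantile normalization. The count was 73 and 123 without heat shock replicates 1 and 2, 247 without osmotic stress replicate 1 and 592 and 574 without oxidative stress replicates 1 and 2. Short or multi-copy rows with the largest differences were the 2 RNase MRP rows and mt-Tc, listed at 0 under osmotic stress, U6#148, listed at 0 after heat shock, and Hist1h2ao and a vault RNA row, at 250 and 12.1 and at 35.1 and 11.9 RPKM under osmotic stress.

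Between heat shock and oxidative stress, Hspa1a, Hspa1b, Hsph1 and Dnajb1 were higher after heat shock by log2 differences of 7.63, 7.61, 4.95 and 4.73. Btg2, Rdm1 and the kinase gene Plk2 were higher under oxidative stress, at 37.4 ± 13.1, 39.8 ± 17.1 and 328 ± 165 RPKM against 2.24 ± 0.135, 3 ± 0.28 and 39.8 ± 6.23 RPKM after heat shock (mean ± SD, n = 2 libraries per group). Btg2 and Rdm1 differed by -3.75 (SE 0.3, limma adjusted p = 0.0026) and -3.46 (SE 0.3, limma adjusted p = 0.0033). Limma called 2273 rows, 925 higher and 1348 lower after heat shock, against 1495 and 1450 with quantile normalization. The count was 107 and 195 without heat shock replicates 1 and 2 and 170 and 804 without oxidative stress replicates 1 and 2. RNase MRP and mt-Tc rows were listed at 0 under oxidative stress, and rows named SNORD58, SNORD60 and SNORD24 were listed at 0 after heat shock and at 663 and 415, 130 and 139, and 139 and 105 RPKM under oxidative stress.

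Between osmotic and oxidative stress, Vmac and Hexim1 were higher under osmotic stress by 2.93 (SE 0.25, limma adjusted p = 0.0073) and 2.84 (SE 0.28, limma adjusted p = 0.011), and Egr1 by 2.27. The call of Egr1 ended with columns scaled to a common sum (limma adjusted p = 0.1) and held in 3 of the 8 fits that left out 1 library. Gdf15 and Hmox1 were higher under oxidative stress, at 15.6 ± 6.96 and 59.5 ± 14.8 RPKM against 0.49 ± 0.0554 and 7.97 ± 2.59 RPKM (mean ± SD, n = 2 libraries per group), log2 differences of -3.96 (SE 0.32, limma adjusted p = 0.0073) and -2.84 (SE 0.27, limma adjusted p = 0.01). Limma called 3101 rows, 2276 higher and 825 lower under osmotic stress, where the median of all rows was 0.27. The split was 427 and 1316 with median-of-ratios scaling, 63 and 681 with columns scaled to a common sum and 631 and 784 with quantile normalization. The count was 45 without osmotic stress replicate 1, 14 and 411 without oxidative stress replicates 1 and 2, and 188 and 189 without heat shock replicates 1 and 2. Rows of short or multi-copy RNAs again led, with Hist1h2ao at 250 and 12.1 RPKM and a row of Mir684-1 at 2240 and 42.5 RPKM under osmotic stress, and SNORD63 listed at 0 there. The call of the Mir684-1 row ended with median-of-ratios scaling (limma adjusted p = 0.071) and with quantile normalization (0.07).

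The gene tables can show transcription past gene ends only as reads in the next gene, so genes that start just downstream of an expressed gene were tested as sets. With neighbours from the GENCODE M21 annotation, 1052 tested genes started within 10 kb of the end of a gene on the same strand with a mean of at least 5 RPKM, and 1204 had such a neighbour on the opposite strand. The median of the same-strand set lay 0.04, 0.05 and 0.00 above that of other genes for heat shock, osmotic and oxidative stress on the log2 scale, and that of the opposite-strand set -0.06, 0.01 and -0.01 from it. Of the same-strand set 2.19%, 1.14% and 3.33% were called higher, against 2.57%, 0.38% and 1.15% of other genes. The shares were 1.66%, 0.415% and 1.41% for the opposite strand, against 2.61%, 0.431% and 1.28%, and shares were not tested. None of the 6 camera tests was called, with adjusted p of 0.94, 0.24 and 0.51 for the same strand and 0.47, 0.94 and 0.94 for the opposite strand, each 0.98 with an estimated correlation. The lowest unadjusted p was 0.039, for osmotic stress on the same strand, and 2 of the 6 had direction down. Without untreated replicate 1 that set's difference was 0.076 with adjusted p = 0.044, and the same-strand sign turned without untreated replicate 2 for heat shock (-0.001), and without untreated replicate 2 or oxidative stress replicate 1 for oxidative stress (-0.038 and -0.048). On the opposite strand the sign turned for osmotic stress without untreated replicate 2 (-0.004) or osmotic stress replicate 1 (-0.016), and for oxidative stress without untreated replicate 1 (0.002) or oxidative stress replicate 2 (0.010).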

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

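The tests below of depth and of neighbouring genes by strand were chosen after the results were seen, while the test by exon length was written down first.

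In all, 4 rows were singled out because heat shock and another stress moved them in opposite directions, each past the limma threshold. The difference between the stresses then follows from how they were picked and is no separate evidence. The row 9430037G07Rik fell by 1.09 after heat shock and rose by 1.62 under osmotic stress on the log2 scale, a difference of -2.71. Rdm1 fell by 1.65 after heat shock and rose by 1.81 under oxidative stress, a difference of -3.46. Pvr, which encodes a cell adhesion receptor, fell by 0.74 after heat shock and rose by 1.23 under oxidative stress, a difference of -1.96. Hspa1b rose by 6.22 after heat shock and fell by 1.39 under oxidative stress, a difference of 7.61, and its value is uncertain because Hspa1a is a near-identical copy. Explanations for these 4 rows were not tested.

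Rows at 0 in untreated fibroblasts gained values under every stress. Of 1114 olfactory receptor rows, which the comparisons hardly use, 19 and 24 were above 0 in the untreated libraries. The numbers were 49 and 38 after heat shock, 65 and 45 under osmotic stress and 98 and 62 under oxidative stress (replicates 1 and 2). Of 5366 protein-coding rows at 0 in both untreated libraries, 537 (10%) were above 0 in both heat shock libraries, 479 (8.93%) in both osmotic stress libraries and 818 (15.2%) in both oxidative stress libraries. In the reverse direction, 90 of 4325 (2.08%), 71 of 4334 (1.64%) and 38 of 3769 (1.01%) rows at 0 under the stress were above 0 in both untreated libraries. Any value above 0 counted, with no floor at 1 fragment. Listed values can lie far below 1 fragment, as for Map2 at 2.08e-127 and 6.61e-09 RPKM under osmotic stress.

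By the values taken as 1 fragment, no stress library was more than 1.06 times as deep as the untreated library of its table. Those values were sought only within a fixed range and rest on 8 and 14 rows in untreated replicates 1 and 2. Several fragments of a much deeper library could fall in that range, so deeper sequencing stays open. Silent rows within 10 kb downstream of an expressed gene on the same strand gained values more often than those with the neighbour on the opposite strand after heat shock (50.8% of 61 against 22.6% of 62, odds ratio 3.54, Fisher's exact p = 0.0014) and under osmotic stress (62.3% against 24.2%, odds ratio 5.18, Fisher's exact p = 2.5e-05), which is consistent with transcription past gene ends. Under oxidative stress the shares were 60.7% and 51.6% (odds ratio 1.45, Fisher's exact p = 0.37), which leaves that explanation open there. With neighbours of at least 1 RPKM the odds ratio was 1.89 (Fisher's exact p = 0.042). With neighbours of at least 5 and 1 RPKM it was 1.48 and 1.56 within 50 kb (Fisher's exact p = 0.066 and 0.009) and 1.48 and 1.53 within 100 kb (Fisher's exact p = 0.036 and 0.0053). Reads spread evenly over the genome are argued against for oxidative stress, since rows near an expressed gene on either strand gained values more often than other silent rows of like exon length (56.1% of 123 against 14% of 4731, Mantel-Haenszel odds ratio 9.43). This odds ratio was 6.77 for heat shock and 9.19 for osmotic stress. The rows were matched on exon length only and not on how uniquely reads map to them. Whether the odds ratio differs between stresses was not tested, and the counted strand and other sources of reads stay open.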

How the results depend on the processing

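Of the alternatives here, doubtful zeros set to missing and protein-coding rows only were chosen after the data were seen; the cause was not tested unless given.

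The 2 added alternatives gave 372 and 462 changed rows for oxidative stress against untreated cells, and doubtful zeros missing gave 240 for osmotic stress. The oxidative stress count was 880 with no filter, 33 with 2 RPKM in at least 2 libraries, 514 with median-of-ratios scaling and 375 with no mean trend. Median-of-ratios scaling gave 560 rows between heat shock and osmotic stress and 1743 between osmotic and oxidative stress. Columns scaled to a common sum gave 364 for heat shock against untreated cells, 546 against osmotic and 533 against oxidative stress, and 744 between osmotic and oxidative stress. Quantile normalization gave 547 between heat shock and osmotic stress and 1415 between osmotic and oxidative stress, and r = 0.257 between heat shock and oxidative stress. Under median-of-ratios scaling 956 of the 1063 heat shock calls, 90 of the 111 osmotic and 235 of the 238 oxidative stress calls were kept.

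With only the 2 groups compared, which leaves fewer libraries to estimate the spread, counts were 241, 2 and 5 for heat shock, osmotic and oxidative stress against untreated cells, 60 between heat shock and osmotic stress and 10 between osmotic and oxidative stress. With the replicate number as a replicate block they were 2124, 433 and 412 against untreated cells, and 2483, 3836 and 5228 for heat shock against osmotic, heat shock against oxidative and osmotic against oxidative stress. Deviations of replicate 1 correlated between groups by 0.062 to 0.264, and the labels do not say that equal numbers pair samples. Some genes, not counted here, differed between replicates alike in all 4 groups. Col3a1 was at 71 and 135 RPKM in untreated cells, 45.3 and 99.7 after heat shock, 48.3 and 123 under osmotic and 37.9 and 92.1 under oxidative stress. Without the block such differences count as spread, so a gene or list not called in the main fit may be called with it. Under oxidative stress the block gave the mitosis list camera adjusted p = 3.9e-05 with 1 gene that fell, in place of 0, and 9 histone genes that fell, in place of 0. Also under oxidative stress it gave the matrix list adjusted p = 0.0015 in place of 0.055, with 0 genes past the threshold, and termination factors 0.06 in place of 0.044. Under osmotic stress the hypoxia list had 0.05 in place of 0.073. After heat shock the block gave 5 DNA replication genes that fell (camera adjusted p = 0.056) and 1 NF-kB target that fell, in place of 0 each. It also gave 1 mitosis gene that rose, in place of 0, and 9 matrix genes that fell, in place of 3. With an estimated correlation 0 lists were called for heat shock, 0 for osmotic and 0 for oxidative stress.

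Differences of neighbour sets that reversed were never called: on the opposite strand -0.001 (osmotic) and 0.003 (oxidative stress) with median-of-ratios scaling and 0.002 (oxidative stress) within 5 kb, and on the same strand -0.023 within 50 kb and -0.017 with neighbours of at least 1 RPKM (both oxidative stress). Named genes that reversed under a scaling had not passed in the first place, and the median of all rows moves with the scaling. After heat shock Ccl2 was 0.27 with columns scaled to a common sum and 0.43 with quantile normalization, Top2a 0.21 and 0.33, and Tef 0.00 with median-of-ratios scaling and 0.37 with the common sum. Under osmotic stress, values with median-of-ratios scaling, the common sum and quantile normalization were -0.02, -0.47 and -0.08 for Plk2, -0.07, -0.52 and -0.05 for Top2a, -0.14, -0.59 and -0.12 for Pcna and -0.09, -0.54 and -0.11 for Mt1. With the common sum Ccl2 was -0.06, Hist1h4d -0.22, Rpl8 -0.38, Ldha -0.39 and Tef -0.41. Under oxidative stress Xrn2 was 0.06, 0.10 and 0.05. Over all alternatives, 3405 of 4447 values of named genes kept direction and side of the threshold, 995 kept direction only and lost the call, 5 gained a call and 42 reversed.

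Leaving out 1 library, with a lone library assumed to vary like the others, gave 73 to 1231 changed rows for heat shock, 8 to 777 for osmotic and 11 to 229 for oxidative stress, 73 to 1138 between heat shock and osmotic, 107 to 2307 between heat shock and oxidative and 14 to 2890 between osmotic and oxidative stress. These fits kept the 16056 rows, a choice made after both ways were seen. With the filter applied again the 6 ranges were 40 to 1279, 5 to 782, 4 to 110, 27 to 1144, 57 to 2356 and 0 to 2895, and most counts without a library of a compared stress were lower. Without oxidative stress replicate 2, limma called 43 in place of 229 rows for oxidative stress, 417 in place of 804 between heat shock and oxidative and 100 in place of 411 between osmotic and oxidative stress. Without heat shock replicate 2 it called 40 in place of 117 for heat shock and 27 in place of 123 between heat shock and osmotic stress. Without osmotic stress replicate 1 the osmotic stress count was 6 in place of 22. Without oxidative stress replicate 1 it called 0 in place of 14 between osmotic and oxidative stress, where 4088 rows had an unadjusted p under 0.05. Lists called were 7 to 10, 6 to 9 and 11 to 15. Correlations were 0.352 to 0.528 for heat shock and osmotic, 0.242 to 0.419 for heat shock and oxidative and 0.147 to 0.363 for osmotic and oxidative stress. Unchanged groups gave 0.666 to 0.668 without an untreated library, 0.406 to 0.412 without a library of a stress of the pair and 0.499 to 0.502 without one of the other stress. Differences of covariance from simulations were 0.1 to 0.166, 0.026 to 0.0578 and -0.00299 to 0.0149. Neighbour differences were -0.001 to 0.047 (heat shock), 0.025 to 0.076 (osmotic) and -0.048 to 0.047 (oxidative stress) on the same strand, and -0.016 to 0.026 (osmotic) and -0.035 to 0.010 (oxidative stress) on the opposite strand. Genes without a call that changed sign were Tef after heat shock (-0.30 to 0.09), under osmotic stress Cd68 (-0.58 to 0.16), Mt1 (-0.24 to 0.50), Pcna (-0.12 to 0.27), Plk2 (-0.36 to 0.76), S100a4 (-0.20 to 0.14), Sqstm1 (-0.30 to 0.09) and Top2a (-0.33 to 0.62), and under oxidative stress Actb (-0.76 to 0.06), Aqp1 (-0.52 to 0.00), Srsf1 (-0.10 to 0.17) and Xrn2 (-0.24 to 0.05). Library depth in reads is unknown, so its effect on low genes cannot be given.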

Other observations

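The tests of summed rows of RNase MRP RNA, of scaling and of single osmotic stress libraries were chosen after the results were seen, and that of zeros among short RNAs was written down first.

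Low genes just downstream of an expressed gene were counted by strand. Of 207 tested rows under 1 RPKM in untreated cells with an expressed upstream neighbour within 10 kb on the same strand, 32 (15.5%) rose under oxidative stress, with a median log2 change of 0.80 against 0.13 for other rows of that level. With the neighbour on the opposite strand, 11 of 151 (7.28%) rose, with a median of 0.49. After heat shock 5.8% and 3.97% rose, and under osmotic stress 2.9% and 0.662%. This split by level was made after the values were seen, and the difference between strands was not tested here. Rows this low in untreated cells can enter the test through high values under stress, which favours rises.

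The RNA component of RNase MRP was listed at 80000 and 52700 RPKM on its highest row after heat shock and at 0 in the other 6 libraries. Reads moved between rows of the same RNA are argued against, since outside heat shock its 3 rows summed to 0 percent of the lowest heat shock library. Failed estimates remain a candidate explanation: among values whose partner library held at least 5 RPKM, 8.73% of 2714 were 0 on short RNA rows and 0.00182% of 55029 on protein-coding rows, an odds ratio of 5270. These shares cannot show a failure in both libraries of a group, for either kind of row. A change of this RNA with heat shock was not tested apart from that and stays open.

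More rows differed between osmotic and oxidative stress, 3101, than between either and untreated cells. Scaling of the deposited columns is argued against as the whole cause of this larger count. With median-of-ratios scaling 1743 rows differed, against 514 for the larger of the other 2 counts. These are counts, and they do not show that the same rows were called. Most of the 3101 rows were higher under osmotic stress, while most of the 1743 were lower there. Which rows were called, and in which direction, therefore depended on the scaling. Whether 1 osmotic stress library gives the count stays open. It was 45 without osmotic stress replicate 1 and 2890 without osmotic stress replicate 2, but also 14 and 411 without oxidative stress replicates 1 and 2, and 188 and 189 without heat shock replicates 1 and 2, which are not in the comparison. With the filter applied again in each fit, limma called 28 and 2895 without osmotic stress replicates 1 and 2, 252 without either heat shock library, and 0 and 100 without oxidative stress replicates 1 and 2 (4088 and 4756 rows with an unadjusted p under 0.05). Against untreated cells, 0 rows were called in opposite directions by these 2 stresses, but few rows were called in either. Between tables the covariance of their log2 changes was 0.0172 and -0.0236, of either sign. Opposite responses of the cells were not tested beyond this and stay open.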
